A study of Mus musculus with 6 samples.

How the data were processed

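Spleen RNA from 6 female BALB/c mice at postnatal day 21 was measured on CodeLink mouse whole genome arrays, which carry 1 oligonucleotide probe per spot and were read in 1 colour (Cy5), per the labels. There were 3 control animals and 3 animals exposed to 0.1 mM lead (Pb) from gestation day 8. The deposited values are probe intensities on a linear scale, as their size and the few values at or under 0 show. The median intensity of each array lay between 0.972 and 0.987, so the authors' values appear to be divided by a median per array. The scanner software, the background correction and the exact normalisation are not given in the sources used here. The number of arrays limits the precision, and no detection calls were used, so levels near the bottom of an array have no stated error. The wider values of Pb replicate 2, given below, limit it too.

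The table held 35587 probes. By the platform annotation, 21615 had 1 gene symbol, 681 had several and 13291 were not listed. No gene was named from a probe with several symbols. The entrez identifier of 21487 of the 1-symbol probes was found in the RefSeq gene table of GRCm38.p6, and no symbol changed. That table served for names alone, and no coordinates are given because the sources name no genome build. Intensities at or under 0, between 151 and 711 per array, were raised to the 1st percentile of the positive values of their array, and all values were set to log2.

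The comparison fixed before the data were examined used all 6 arrays. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the probes tested). Probes with a mean log2 intensity at or above the 30th percentile were kept. Gene lists were fixed at the same time and tested with limma's camera at its preset inter-gene correlation of 0.01, with 1 probe per gene, the one with the highest mean. Of these lists, 29 had at least 5 measured genes. The spread is that between the samples the labels give as separate animals.

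Reading the values showed 3 departures from what that design assumes. The values of Pb replicate 3 did not follow the probes of any other array (r with the controls of 0.045 to 0.051 across probes, against 0.94 between controls). Its values within an array row had a median r of -0.01 with the controls, whereas the means of its array rows had r = 0.97. No fixed offset, mirror image or sorting by probe identifier, accession, symbol or entrez identifier restored the order, and it was not restored by matching values to other arrays, which would have built in the answer. In array rows 402 to 409 (638 probes) the controls did not follow each other either, with r between -0.05 and 0.10. The level of Pb replicate 2 changed along the array rows, by medians of 20 rows from -2.44 to 2.36 on the log2 scale.

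A second fit was therefore made, and it departs from the design fixed beforehand. It left out Pb replicate 3 and array rows 402 to 409, which left 34949 probes and 5 arrays. From each array the smooth part of its deviation from the mean of the 3 controls and Pb replicate 1 was removed in 2 rounds (mgcv 1.9.3, function bam, tensor products of array row with level and of array row with array column, with 40, 6 and 8 basis functions for row, level and column). The r of Pb replicate 2 with the controls was 0.68 before and 0.94 after. That gain is partly built in, since what was removed is a deviation from a mean that includes the controls. The deviations of Pb replicate 2 stayed wider, with a median absolute deviation, scaled to match an SD, of 0.59 against 0.24 to 0.29 in the other arrays. They were taken from a mean that includes the other arrays and not Pb replicate 2, which adds to that gap. After the filter 24464 probes were tested.

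That fit was chosen after the data had been seen, and after the calls of 8 fits had been looked at. The 6 arrays as deposited gave 0 probes past the adjusted threshold. The 5 arrays without correction gave 0. With a coarser surface of 15 basis functions and all array rows they gave 15, and with array weights in addition 0. The 4 arrays without Pb replicate 2, corrected in that way, gave 2. With array rows 402 to 409 left out, surfaces of 15, 40 and 80 basis functions gave 15, 14 and 15. The surface of 40 was kept because the coarser one left a dip in Pb replicate 1 near array row 130, but its calls were known when it was kept.

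The rule for the genes named was fixed before the data were examined. It takes the 12 largest rises and 12 largest falls past adjusted p of 0.05. Places left go to the smallest p among genes whose groups do not overlap with a fold of at least 1.5, and these are said not to pass. It adds 4 members of each list that passes and 2 of other lists described, genes known to respond to lead, Il4 and Ifng, X- and Y-linked genes, and in lists of other organs the 4 members with the highest single array. It was applied to the fit of 5 arrays. No probe with a single symbol was found for Ifng.

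The fit was tested on simulated arrays built from the real levels and surfaces, with 24464 probes. Changes of 1 on the log2 scale were called in 10.2% of the probes, of 2 in 91.3%, and of 4 and 6 in 100%. Among 24241 unchanged probes 2 were called. The position effect put in was the surface fitted to the real arrays, and the same smoother removed it, so its recovery was built in. Position faults that are not smooth were not simulated, so the 2 false calls do not test the correction against them. The simulated noise had 1 spread per array at every level. In the data the control SD differed between probes, with a median of 0.16 but 0.49 for Amy2a5, 0.81 for Cela3b and 0.15 for Spink1. The simulated shares may therefore not hold for probes that are dim in controls. Alternatives fixed beforehand covered normalisation, filter, values at or under 0, pseudocount, variance model, array weights, replicate number as a block, leaving out each array, and other list tests. The alternatives for 5 arrays and for the position surface were added after the data had been seen.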

Results

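Transcript levels in the spleen were compared between 3 control mice and 3 mice exposed to 0.1 mM Pb from gestation day 8, all female BALB/c at postnatal day 21, to find which splenic genes differ after developmental lead exposure. Each animal had 1 array of 35587 probes. In the array of Pb replicate 3 the values did not follow the probes of the other arrays, so the values of single genes rest on 5 arrays, 3 control and 2 Pb, after correction for position on the array. That set was chosen after the data had been seen. The fit of all 6 arrays, fixed beforehand, is given at the end. Log2 levels are relative to an array median of about 0.

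Of 35 measured pancreatic exocrine genes, 25 were higher in both Pb spleens than in all 3 control spleens. Many of these are genes of the digestive secretion of the pancreas, and some were far higher. Amy2a5, a pancreatic amylase, was at -3.86 ± 0.49 (SD, n = 3) in controls and at 3.40 and 4.54 in the Pb arrays, a log2 difference of 7.84 (SE 0.42, limma adjusted p = 0.0086). Try5, a trypsin, rose by 7.25 (SE 0.35), Cpa1, a carboxypeptidase, by 6.97 (SE 0.38), and Cela3b, an elastase, by 6.75 (SE 0.48). Cpb1 rose by 5.43, Ctrc by 5.13, and the trypsin-like 2210010C04Rik by 4.89. Sycn, a protein of the zymogen granule membrane, rose by 2.96, the trypsin inhibitor Spink1 by 2.66, and the ribonuclease Rnase1 by 2.53. The adjusted p of these 10 genes lay between 0.0086 and 0.0211 (limma). The calls depended on the setting while the direction did not: among the alternatives on 5 arrays, Try5 kept its call in 17 of 20, Amy2a5 in 11 of 17 and Spink1 in 11 of 19, and the largest adjusted p of the 10 genes was 0.380. Their lowest log2 difference was 1.45, for Spink1.

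Of the 29 pancreatic exocrine genes tested, 9 rose, 0 fell and 20 did not pass over all probes. Adjusted over the list alone, 24 rose. Both Pb arrays lay above all 3 controls for 24 of the 29, where chance gives 10%. The filter on the mean lets in a dim gene that is high in Pb, so the tally was also taken over all 35 measured members, of which 25 lay above. Of the 6 under the filter 1 did, Tff2 (log2 difference 2.38), and the others were Bhlha15 (0.89), Zg16 (0.27), Klk1 (0.05), Nr5a2 (-0.17) and Ptf1a (-0.75). Pla2g1b (log2 difference 3.35, adjusted p = 0.051) and Ctrl (3.48, adjusted p = 0.060) did not pass. Reg2, Gp2, Pnliprp2, Erp27 and Serpini2, also products of exocrine cells, did not separate the groups, with log2 differences of 0.56, 0.46, 0.39, -0.25 and -0.27. These genes and those under the filter are named after their values were seen. The mean shift of the list was 2.94 and its median 2.66 (camera adjusted p = 7.53e-40). The call was lost with an estimated correlation (adjusted p = 0.157 with an estimated correlation), and fry gave an adjusted p of 0.0077. Control levels of 8 of the 14 called probes lay under the 30th percentile of the array, where no detection call was at hand, so these folds are uncertain in size. Trypsin and elastase genes are close paralogs, and probes for them can bind more than 1 transcript.

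**Figure D1:**
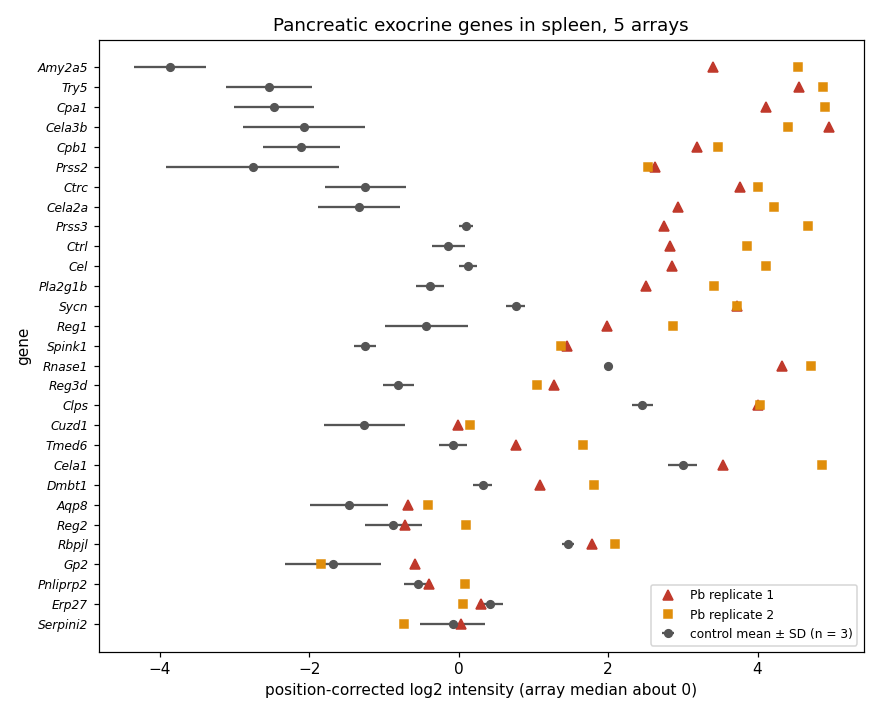
Position-corrected log2 intensity (horizontal axis) of the 29 pancreatic exocrine genes tested (vertical axis), with grey points for the control mean ± SD (n = 3) and a symbol for each Pb array. Both Pb arrays lie above the 3 controls for 24 genes.

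Over all probes, 14 of 24464 passed the adjusted threshold in limma, and all 14 were higher in Pb. Of these, 9 belonged to the exocrine list, 1 was 2210010C04Rik, and 4 had no single gene name, with log2 differences from 2.13 to 6.30. At an unadjusted p under 0.05 there were 965 higher and 803 lower probes, where chance gives 1223 in all. Their sum of 1768 was not firm: it was 979, 787 and 875 without control replicates 1, 2 and 3, 7482 without Pb replicate 1, 915 with array weights and 3606 without position correction. That balance turned in 9 of 20 alternatives, to 725 higher and 1043 lower with scaling to the 75th percentile, 424 and 1981 with a surface without dependence on level, and 1449 and 5595 with a surface over array rows alone. The count of 14 depended on single arrays. It was 4, 2 and 6 without control replicates 1, 2 and 3, and 20 without Pb replicate 2, 17 higher and 3 lower, with Pb replicate 1 as the lone Pb array. It was 2901 without Pb replicate 1, which leaves the wider Pb replicate 2 as the lone one. A lone array is assumed to vary like the controls. It was also 0 without position correction and 0 without the filter on dim probes, 7 with array weights and 22 with a pseudocount.

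Markers of other organs near the spleen did not pass the list test. The mean shift was 0.33 for 7 pancreatic endocrine genes (camera adjusted p = 0.504), 0.32 for 10 adipocyte genes (adjusted p = 0.388), 0.18 for 5 liver genes (adjusted p = 0.664), 0.16 for 15 genes of gastric and intestinal epithelium (adjusted p = 0.705) and 0.14 for 6 muscle genes (adjusted p = 0.705). Among endocrine genes, Neurod1 differed by 0.88 (adjusted p = 0.625) and Ucn3 by 0.60 (adjusted p = 0.633). A difference above 0 was seen in all 7 endocrine and all 10 adipocyte genes tested, but in 12 of 16 and 12 of 15 once those under the filter were included. It was seen in 6 of 17 measured liver, 9 of 18 muscle and 11 of 19 gut genes. Both Pb arrays lay above all controls for 3 of 16 endocrine, 1 of 15 adipocyte, 4 of 17 liver, 3 of 18 muscle and 2 of 19 gut genes. Under the filter Gcg, the gene of glucagon, had -1.62 and Pdx1 -0.72, named after their values were seen. Neurod1 and Pcsk1 had their highest value in Pb replicate 2, 1.77 and 1.08 above the median of the other arrays, while the highest values of Abcc8 (control replicate 1) and Chga (Pb replicate 1) lay 0.34 and 0.25 above it. Among adipocyte genes the excess in Pb replicate 2 was 1.33 for Adipoq, 1.18 for Retn, 1.08 for Pparg and 1.06 for Thrsp. Among gut genes it was 0.60 for Gkn3 in Pb replicate 1 and 0.57 for Lgals4 in Pb replicate 2. Krt19 had 0.55 in control replicate 1 and Cdx2 0.43 in control replicate 3. Among liver genes it was 0.60 for Fgb in control replicate 2, and 0.58 for Cyp2e1, 0.42 for Tat and 0.37 for Ahsg in Pb replicate 2. Among muscle genes it was 0.82 for Mylpf and 0.76 for Mb in Pb replicate 2. Ryr1 had 0.60 in control replicate 1 and Actc1 0.49 in Pb replicate 1.

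Genes that lead is known to act on, or that respond to it, did not pass. Alad, the enzyme of haem synthesis that lead inhibits, had a log2 difference of 0.21 (95% confidence interval -0.35 to 0.78, adjusted p = 0.757). Alas2 had -0.07 (-0.73 to 0.58), Fech 0.32 (-0.32 to 0.97) and Hmox1 0.18 (-0.36 to 0.72). The metallothioneins Mt1 and Mt2 had 0.06 (-0.54 to 0.66) and 0.29 (-1.19 to 1.77). Among 14 genes of haem synthesis and degradation 0 passed, with a mean shift of 0.06 (camera adjusted p = 0.824). Cpox had -0.53 and Ppox 0.55, both with an adjusted p of 0.622. The 26 erythroid genes had a mean shift of 0.10 (adjusted p = 0.705). That shift was -0.27 (adjusted p = 0.0028) without Pb replicate 2 and 0.49 (adjusted p = 0.0036) without Pb replicate 1, so both Pb arrays differed in sign. The 27 genes of the metal and oxidative stress response had a mean shift of 0.06 (adjusted p = 0.90), with Gss at -0.29 and Gclm at 0.36.

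Immune cell lists did not pass either. The mean shift was 0.03 for 22 B cell genes (camera adjusted p = 0.824), -0.01 for 26 T cell genes (adjusted p = 0.705) and 0.19 for 22 genes of neutrophils and myeloid granules (adjusted p = 0.356). The B cell shift was 0.16 (adjusted p = 0.026) without Pb replicate 2. The neutrophil shift was 0.58 (adjusted p = 2.4e-08) without Pb replicate 2 and 0.30 (adjusted p = 0.010) without control replicate 1. In these lists Cd3e, a chain of the T cell receptor complex, differed by 0.73 and Cd247 by 0.62, Blk by 0.52 and Spib by 0.31, and Ms4a3 by 0.80 and Ear6 by 0.59, each with an adjusted p of 0.622 or above. Il4, a cytokine of type 2 helper T cells, lay under the filter at -1.66 ± 0.60 (SD, n = 3) in controls, with a log2 difference of -0.28 and no adjusted p. The 23 genes of type 2 and regulatory cytokines had a mean shift of 0.01 (adjusted p = 0.705), with Retnla at -0.63 and Gata3 at -0.40. The 24 genes of type 1 and inflammatory cytokines had a mean shift of -0.06 (adjusted p = 0.705), with Tnf at -1.17 and Il15 at -0.40. Xist, expressed from the inactive X chromosome, was at 3.27 ± 0.79 (SD, n = 3) in controls and at 3.07 and 3.36 in Pb. The Y-linked Eif2s3y and Uty lay under the filter, and the probe for Kdm5d was at 3.77 in controls, although all animals were female.

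No gene fell past the adjusted threshold. The 12 genes named for the smallest p among lower values did not pass, with adjusted p from 0.060 to 0.622 and log2 differences from -1.07 to -3.31. They were Vmn1r208 (-1.75), Dtx2 (-1.71), Fbxo31 (-1.47), Lrrc36 (-2.23), Tnf (-1.17), Plcg1 (-1.07), C920009B18Rik (-1.08), Plcd1 (-1.21), Prrx1 (-1.48), Selenoh (-3.31), Ddx6 (-1.68) and Bbx (-1.11). Adjusted over the list alone, Tnf had an adjusted p of 0.012 and Plcg1, in the list of cyclic AMP and phosphoinositide signalling (34 genes, mean shift -0.06, camera adjusted p = 0.388), one of 0.030. Of the 12 probes, 6 lay in array rows 121 to 140, Tnf among them, a band that holds 4.64% of the probes tested. Before correction both Pb replicates 1 and 2 were dim there, with median log2 differences from the control mean of -0.67 and -1.13. Outside the band, the probes of Plcg1 and Ddx6 lie side by side in array row 156. Inside it, those of Tnf and Lrrc36 lie close together in array row 134. A fault of the array smaller than the smooth surface was not tested, and the adjusted p of Tnf and Plcg1 does not allow for one. Pb replicates 1 and 2 were at -2.07 and -2.16 for Fbxo31, against -0.64 in controls, and at -1.39 and -1.21 for Tnf, against -0.13.

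**Figure D2:**
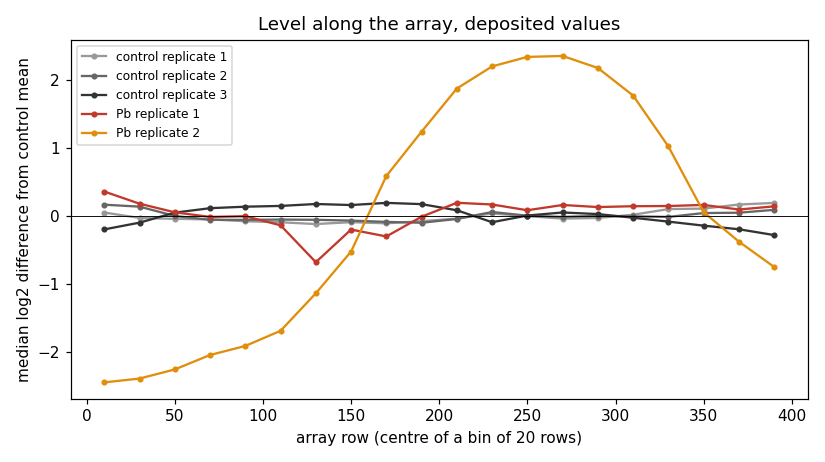
Median log2 difference of the deposited values from the control mean (vertical axis) in bins of 20 array rows (horizontal axis), 1 line per array. Pb replicate 2 runs from -2.44 to 2.36 along the array, and Pb replicate 1 has a dip of -0.67 at rows 121 to 140.

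In the fit of all 6 arrays as deposited, 0 of 24911 probes passed in limma, and the smallest adjusted p was 0.537. At an unadjusted p under 0.05 there were 606 higher and 1161 lower probes, where chance gives 1246. Without the filter on the mean there were 1366 higher and 1267 lower. The balance also turned without control replicate 1 (114 higher, 44 lower), 2 (118 and 49) or 3 (115 and 63). The unadjusted count was 158, 167 and 178 without control replicates 1, 2 and 3, 7427 without Pb replicate 1, 755 without Pb replicate 2 and 3363 without Pb replicate 3. In that fit 3 of 29 lists passed. The exocrine list was higher (30 genes, mean shift 2.20, camera adjusted p = 1.03e-12), and 26 erythroid genes (mean shift -1.83, adjusted p = 0.012) and 14 genes of haem synthesis and degradation (mean shift -2.06, adjusted p = 0.035) were lower. Most lists lay below 0 in that fit: the mean over all 14008 genes was -0.48, 23 of 29 lists had a mean shift below 0, and their median was -0.93. With an estimated correlation 0 lists passed. These shifts include Pb replicate 3, whose values did not follow the probes of the other arrays. Without Pb replicate 3, 1 list passed.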

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

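The alternatives for the 5 arrays were chosen after the data had been seen, except leaving out genes shared between lists, and those for the 6 arrays before. The rise of the exocrine list kept its direction in 24 of 24 alternatives on 5 arrays (mean shift 2.46 to 3.37) and its call in 23, the exception being the estimated correlation (camera adjusted p = 0.157). The estimated correlation, fry, the variance model and leaving out shared genes left the mean shift at 2.94. These could not change the direction and do not test it. Of 2035 comparisons of named genes 1916 stayed on their side of the threshold, 73 lost a call, 46 gained one and 0 reversed, while 118 uncalled differences changed sign. Most named genes had no call to lose, so the 1916 say little on how firm the calls were. Among the alternatives on 5 arrays, the 10 called genes kept theirs in from 11 of 19 (Spink1) to 17 of 20 (Try5). Of 724 comparisons of list shifts, 713 stayed, 6 gained a call and 1 lost it. In the other 4 the sign reversed with a call: erythroid cells -0.27 and cell cycle -0.23 without Pb replicate 2, and erythroid cells -1.83 and haem synthesis and degradation -2.06 in the 6 arrays as deposited. Without Pb replicate 1 erythroid cells (0.49) and cell cycle (0.52) are among the 6 that gained a call. For 5 arrays, the 14 probes past the adjusted threshold became 0 without the filter, 0 without position correction, 7 with array weights, 22 with the pseudocount, and 2 to 2901 with 1 array left out. The 1768 at an unadjusted p became 915 with array weights, 3606 without position correction, 7044 with a surface over array rows alone, and 787 to 7482 with 1 array left out. The 1 list became 0 with an estimated correlation and 1 to 6 with 1 array left out. For 6 arrays, the 1767 probes at an unadjusted p became 530 with array weights and 158 to 7427 with 1 array left out. The 3 lists became 8 without the filter, 1 with the filter at the 50th percentile, 1 with array weights, 0 with an estimated correlation, 0 with fry, and 1 to 4 with 1 array left out. The labels do not say what a shared replicate number means, and deviations of same-numbered arrays had r = 0.06 and 0.01. The deviations of 2 Pb arrays from their own mean mirror each other. These r values are thus not separate checks and say little on pairing. With the replicate block, 1 probe passed in place of 0 and 5 lists in place of 3 for 6 arrays, and 6 probes in place of 14 and 900 in place of 1768 for 5 arrays. Fewer arrays leave fewer degrees of freedom. Leaving out the filter adds tests, from 24464 to at most 34949, but that alone cannot explain the fall to 0. With unchanged p-values, that rise would keep the smallest adjusted p, 0.0086 in limma, under the adjusted threshold. The p-values must therefore have changed as well without the filter, and why was not tested. For the other settings the cause was not tested either. Signal near the bottom of the array limits the folds of genes that are dim in controls.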

Other observations

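The tests reported in this part, splits included, were chosen after the results were seen. The 350 probes within 1 row and 3 columns of the exocrine probes had a median log2 difference of -0.0024 (quartiles -0.22 and 0.24). The exocrine probes, which lie in 27 array rows, had 2.66 (quartiles 1.13 and 4.91). The position correction had already removed smooth brightness from both, and called probes were left out of the neighbours. A median near 0 was thus partly built in, and the comparison shows only that these neighbours did not share the rise. Without position correction the exocrine list had a mean shift of 2.98. A candidate explanation is pancreas tissue taken with the spleen, since the tail of the pancreas lies against it. Of the 35 measured exocrine genes 25 lay above all controls in both Pb arrays, and no pancreas array was at hand to say how bright the probes of the other 10 would be. By the same rule 3 of 16 measured endocrine and 1 of 15 adipocyte genes lay above. A difference above 0 was seen in 12 of 16 and 12 of 15, Gcg (-1.62) and Pdx1 (-0.72), both under the filter, not among them. Neither list passed (limma's camera, adjusted p = 0.504 and 0.388). No insulin gene was among the 16, so the endocrine genes say little here. A response of the spleen to Pb stays open as well: the differences of both Pb arrays had r = 0.96 across the 35 genes, against a median of 0.11 (95th percentile 0.50) simulated with no change and the same shared controls, with a covariance of 5.63 against 0.07, and carried-over tissue would give this too. With 2 exposed animals these explanations cannot be told apart.

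The values of Pb replicate 3 did not follow the probes, but its array row means had r = 0.97 with the controls, against -0.0046 for a control shuffled over the whole array. This is consistent with values placed in another order within their array rows, though the order itself was not found. Its values sorted within rows had r = 0.99, but the shuffled control reached 0.95, so that measure says nothing on failed labelling or hybridisation, which stays open. No biological explanation was tested.

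Of the 12 genes named for lower values, 6 lay in array rows 121 to 140. Uneven brightness of Pb replicate 1 there may play a part, but the values do not decide it. Pb replicate 2 was dim there too before correction (median log2 difference -1.13, against -0.67 for Pb replicate 1). Over all probes at an unadjusted p under 0.05, the band held 6.72% of the lower and 6.22% of the higher ones, against 4.64% of those tested, but the position correction had already removed the smooth part of the dip, so like shares say little. Dim probes of Pb replicate 1 spread more widely inside the band (SD of the difference from controls 0.53) than elsewhere (0.43). Pb replicates 1 and 2 were alike for Fbxo31 (-2.07 and -2.16) and Tnf (-1.39 and -1.21), which is partly built in, since the genes were named for being low in both arrays. Plcg1 and Ddx6 lie side by side in array row 156, outside the band, and Tnf and Lrrc36 close together in array row 134. A local fault that the smooth surface leaves in place was not tested and stays open for these genes.

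Whether Pb replicate 3 also held the exocrine rise was asked without its order, from the array rows that hold the exocrine probes. In all, 12 versions of that test were run, with counts above a level or sums per row, and different floors. Of the 3 sets of probes, 1 was the list fixed beforehand, after the filter. Another was picked by hand, and the last held the list members that had risen, so both were chosen from these data. In Pb replicate 3, 8 of 12 had a permutation p under 0.05, and p ran from 0.0005 to 0.412. Sums without a floor passed in control replicate 1 (2 of 12 versions in all). They also passed in a shuffled control with no rise added (permutation p = 0.0009). That shuffled control was control replicate 1 with its values shuffled within array rows. Such a shuffle leaves row sums unchanged, so it is the same array with another selection of list members and not a separate check. With floors of -1, 0 and 1 the shuffled control gave permutation p = 0.200, 0.179 and 0.304, a simulated rise of 3 on the log2 scale passed at 4 of 4 settings, and control replicates 2 and 3 passed in 0 of 12 versions. Leaving out sums without a floor, 5 of 9 versions passed in Pb replicate 3 and 0 of 9 in each control. With the list fixed beforehand and floors of -1, 0 and 1, Pb replicate 3 gave permutation p = 0.018, 0.075 and 0.412. The versions were not fixed beforehand and do not give 1 answer. Only 6 of 12 passed in Pb replicate 1 and 2 of 12 in Pb replicate 2, which have the rise, so the question stays open.

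For the 6 arrays as deposited, 3 against 3 make 10 splits, too few for a share under 0.05. The probes past the adjusted threshold were 0 in all 10 splits, highest other 0. The unadjusted count was 1767 in the real split, 1 of 10 with as many, and 628 in the highest other. The splits with Pb replicates 2 and 3 in the same group, the real one among them, gave 1767, 628, 434 and 372. The rest gave 51 to 96. The lead of the real split can therefore not be told apart from the departures of those arrays. The lists that passed were 3 in the real split and 5 in the highest other, and 4 of 10 splits gave as many.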
